A study of Homo sapiens with 7 samples.

How the data were processed

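Gene expression was measured in fresh-frozen human autopsy brain tissue with Affymetrix 3' expression arrays, to which biotin-labelled cRNA made from total RNA had been hybridised. There were 7 arrays: 2 of control white matter, 1 of active plaque, 2 of chronic active plaque and 2 of chronic plaque from multiple sclerosis brains. The deposited values are intensities on a linear scale, 1 per probe set and array, which the authors made with Affymetrix Expression Console. The summarisation algorithm, the version and the scaling target are not given in the sources used here, and neither are detection calls. Array means lay close together, so the values appeared scaled between arrays. The deposited table held 33398 probe sets, and each of them reached 100.02 on at least 1 array, so dim probe sets had already been removed by an unstated rule.

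Values were analysed as log2(intensity + 16), with no further scaling. Probe sets were assigned to genes by the annotation of the array platform. Of the probe sets, 26841 named 1 gene, 1254 named several genes and 5303 named none, and only those naming 1 gene were used for genes. XIST and TSIX, Y-linked genes and genes known to follow a common deletion or haplotype of single persons were left out (61 probe sets of 27 genes), which left 26792 probe sets of 14288 genes. Each gene was represented by its probe set with the highest mean over all arrays. Genes whose mean lay under the 40th percentile were left out, and 8573 were tested.

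A linear model with 1 mean per group was fitted to all 7 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with trend=TRUE), and p-values were adjusted by the method of Benjamini and Hochberg over all genes tested, with a threshold of 0.05. The single active plaque array was assumed to vary like the replicated groups. There were 5 comparisons: chronic active plaque against control, chronic plaque against control, active plaque against control, chronic active against chronic plaque, and active plaque against the mean of chronic active and chronic plaque. The moderated tests had 6.44 degrees of freedom in total, and the median standard error of a log2 fold change was 0.402 for the comparisons of replicated groups and 0.492 for active plaque against control. Tested on simulated data with 200 changed genes among 8573, the comparison of chronic active plaque with control recovered 6% of genes changed by 1 on the log2 scale, 66% of those changed by 2, 98% by 3 and 92% by 4, with 9 false calls. The simulated noise was independent and had 1 spread per gene in all groups. In the data the standard deviation of log2 differences was 0.41 between the controls, 1.15 between the chronic active arrays and 1.23 between the chronic arrays. Recovery and false calls in the data can therefore differ from the simulated ones. A gene is said to have risen or fallen where it passed the adjusted threshold.

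The 27 gene lists were written before the data were examined, as were the comparisons, the tests, the rule for named genes and the alternatives, except where the text says otherwise. They hold markers of myelin and mature oligodendrocytes, oligodendrocyte precursors, astrocytes, reactive astrocytes, homeostatic microglia, phagocytic macrophages, T cells, B and plasma cells, neutrophils and monocytes, red cells, endothelium, mural cells, neurons and synapses. Further lists hold genes of the CD47 axis, MHC class I, MHC class II, complement, interferon response, chemokines with cytokines and adhesion, cholesterol synthesis, extracellular matrix, cell cycle, heat shock with immediate early genes, hypoxia, metallothioneins and mitochondrial respiration. Lists can share members: the protease gene CTSS, which is not itself an MHC gene, is in both the MHC class II and the phagocytic macrophage lists. Lists with at least 3 measured members were tested with camera in limma, at a preset correlation of 0.01 and again with an estimated correlation, adjusted by Benjamini-Hochberg over all lists and comparisons. At the preset correlation the p-values rest on the number of genes and do not measure the spread between samples. The run with an estimated correlation takes its degrees of freedom from the arrays, so it has little power. For homeostatic microglia in chronic active plaque that correlation was -0.03, yet the unadjusted camera p went from 3.07e-05 to 0.0224. No list passed in that run, with a smallest camera adjusted p of 0.315, or 0.24 without the filter. T cells, B and plasma cells and red cells had 0, 2 and 1 members above the filter and were tested only without it. Counts adjusted over the list alone use the p-values of the list's own members.

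For each comparison the named genes were CD47, the 6 genes with the largest rise and the 6 with the largest fall among those that passed and whose arrays on one side all lay above those on the other, and the 3 members with the smallest p in the direction of each called list. Where fewer than 12 genes passed, those with the smallest p filled up to 12. Genes outside this rule are said to be named after their values were seen. Reported ± values are standard deviations of intensities.

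Chance overlap of the comparisons sharing the controls was simulated with 100 draws of unchanged groups. The alternatives were median centring, quantile normalization, no filter, a filter at the 60th percentile, the mean of a gene's probe sets, every probe set with its own test, no variance trend, only the groups compared, a pseudocount of 1 or 64, the replicate number as a block, and each array left out in turn. Pairing the plaque arrays by their likeness, the replicate block on all arrays with active plaque at its middle, setting each plaque class against a different control, and the other pseudocounts for lymphocyte genes without the filter were added after seeing the data. No group had enough arrays to test other splits of the samples against controls. Intensities carry no counts, so no counting interval was given. Genome coordinates are left out because the files name no genome build. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.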

Results

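RNA was extracted from fresh-frozen human autopsy brain tissue and hybridised, as biotin-labelled cRNA, to 7 Affymetrix expression arrays. The arrays fell into 4 groups named by histology. The control group held 2 arrays of white matter from healthy brains. The other groups were lesions of multiple sclerosis, an inflammatory disease in which the myelin sheath around axons is lost. There was 1 array of active plaque, taken here as an early stage, and 2 arrays of chronic active plaque, in which myelin had been lost while inflammation went on. A further 2 arrays came from chronic plaque, in which inflammation had subsided and glial scarring remained. The design text calls the first plaque class acute and the sample labels call it active. The labels do not say whether the lesions lay in white or grey matter, or whether the arrays came from separate donors, so p-values measure only the spread between these samples, which may be technical. Active plaque had no replicate, and the number of arrays limits the precision of every comparison.

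The deposited table held 33398 probe sets, each reaching an intensity of at least 100.02 on 1 or more arrays. Median intensities were 394 and 387 for the controls, 363 for active plaque, 373 and 313 for chronic active plaque, and 299.6 and 374 for chronic plaque. Between 12.8% and 24.8% of probe sets lay under an intensity of 100 on a given array. After restriction to 1 probe set per gene and removal of dim genes, 8573 genes were tested.

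The control arrays resembled each other closely, while the arrays of one plaque class did not. Across probe sets, which are not independent replicates, Pearson's r of log2 intensities was 0.976 between the controls, and 3.41% of probe sets differed by more than 2-fold. It was 0.840 between the chronic active arrays, with 37.2% of probe sets beyond 2-fold, and 0.821 between the chronic arrays, with 39.8%. The closest plaque pairs crossed the class labels. Chronic active replicate 1 and chronic replicate 2 had r = 0.947, and chronic active replicate 2 and chronic replicate 1 had r = 0.949. Active plaque lay nearest to chronic active replicate 2 (r = 0.862), control replicate 1 (r = 0.852) and chronic replicate 1 (r = 0.851).

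**Figure D1:**
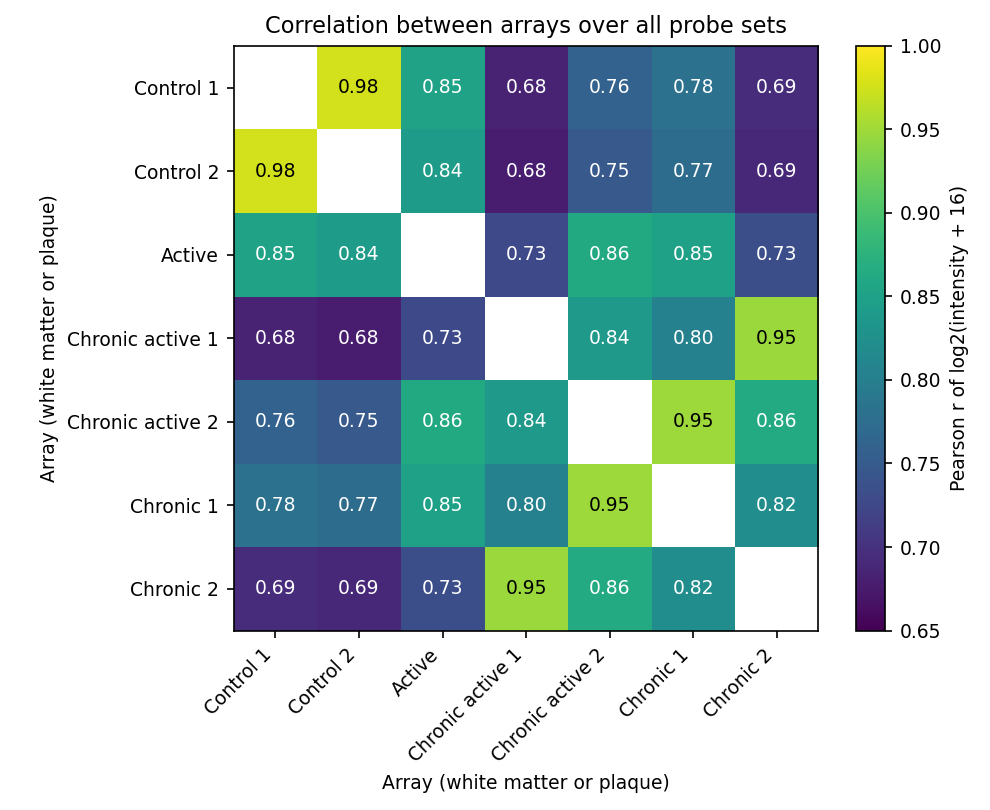
Pearson correlation of log2 intensities across probe sets for every pair of the 7 arrays, coloured by r. The control pair reaches 0.976, whereas the pairs within chronic active and chronic plaque (0.840 and 0.821) lie below the crossed pairs of these classes (0.947 and 0.949).

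The series title concerns CD47, a cell-surface protein that binds SIRPA on phagocytes and restrains engulfment, and its level was compared between all groups. By its brightest probe set, CD47 did not pass the test in any comparison. Its intensity was 6384 ± 386 in control (SD, n = 2), 5886 in active plaque, 8735 ± 3140 in chronic active plaque (SD, n = 2) and 7854 ± 1470 in chronic plaque (SD, n = 2). The log2 fold change against control was 0.41 (SE 0.35, limma adjusted p = 0.447) in chronic active, 0.29 (SE 0.35, adjusted p = 0.604) in chronic and -0.12 (SE 0.43, adjusted p = 0.953) in active plaque. It was 0.12 (SE 0.35, adjusted p = 1) between chronic active and chronic plaque and -0.46 (SE 0.39, adjusted p = 0.538) between active plaque and the mean of the later classes. These values depended on single arrays. With 1 array left out in turn the log2 fold change ranged from 0.03 to 0.78 in chronic active, from 0.095 to 0.48 in chronic and from -0.18 to -0.05 in active plaque against control, from -0.65 to -0.27 for active against later plaque and from -0.26 to 0.49 for chronic active against chronic plaque, which turned negative without chronic active replicate 2 (-0.26) and without chronic replicate 2 (-0.07).

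Of the 6 CD47 probe sets, another one fell. The probe set with the largest fall had an intensity of 1122 ± 209 in control (SD, n = 2) and 120.5 ± 52 in chronic active plaque (SD, n = 2). In a fit of every probe set its log2 fold change was -3.10 (SE 0.47, adjusted p = 0.0156) in chronic active and -2.81 (SE 0.47, adjusted p = 0.0223) in chronic plaque. It read 83.67 on chronic active replicate 2 and between 129.8 and 162 on the other chronic active and chronic arrays. At this low signal the size of the fall is uncertain, and no other pseudocount was tried in that fit. In active plaque it read 200.9, a log2 fold change of -2.38 (SE 0.57, adjusted p = 0.272). A further probe set had log2 fold changes of -2.34 (adjusted p = 0.145) and -1.83 (adjusted p = 0.25) in chronic active and chronic plaque, and the remaining ones, apart from the brightest, lay between -1.29 and 0.31. With the mean of the gene's probe sets in place of the brightest one, the CD47 log2 fold change reversed to -0.997 in chronic active plaque (adjusted p = 0.111) and to -1.07 in chronic plaque (adjusted p = 0.0994). It also reversed for active against later plaque, to 0.54 (adjusted p = 0.505).

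Among 9 measured members of the CD47 axis list, which holds CD47, its ligands and receptors, 1 passed the test in chronic active and in chronic plaque, also when adjusted over the list alone (1 of 9). That gene, THBS2, encodes the CD47 ligand thrombospondin 2 and was named after its values were seen. It fell by 3.06 on the log2 scale in chronic active (SE 0.29, adjusted p = 0.00251) and had a log2 fold change of -3.12 in chronic plaque (SE 0.29, adjusted p = 0.00316). In active plaque THBS2 had a log2 fold change of -1.53 (SE 0.36, adjusted p = 0.184), and active plaque exceeded the later classes by 1.56 (SE 0.33, adjusted p = 0.0493). SIRPA, the CD47 receptor, also named after its values were seen, had log2 fold changes of 0.90 (SE 0.31, adjusted p = 0.0882) in chronic active and 0.56 (SE 0.31, adjusted p = 0.252) in chronic plaque. The list as a whole was not called in chronic active (median -0.20, camera adjusted p = 0.317), chronic (-0.23, adjusted p = 0.244) or active plaque (0.17, adjusted p = 0.832), where the test pointed down against a positive median.

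**Figure D2:**
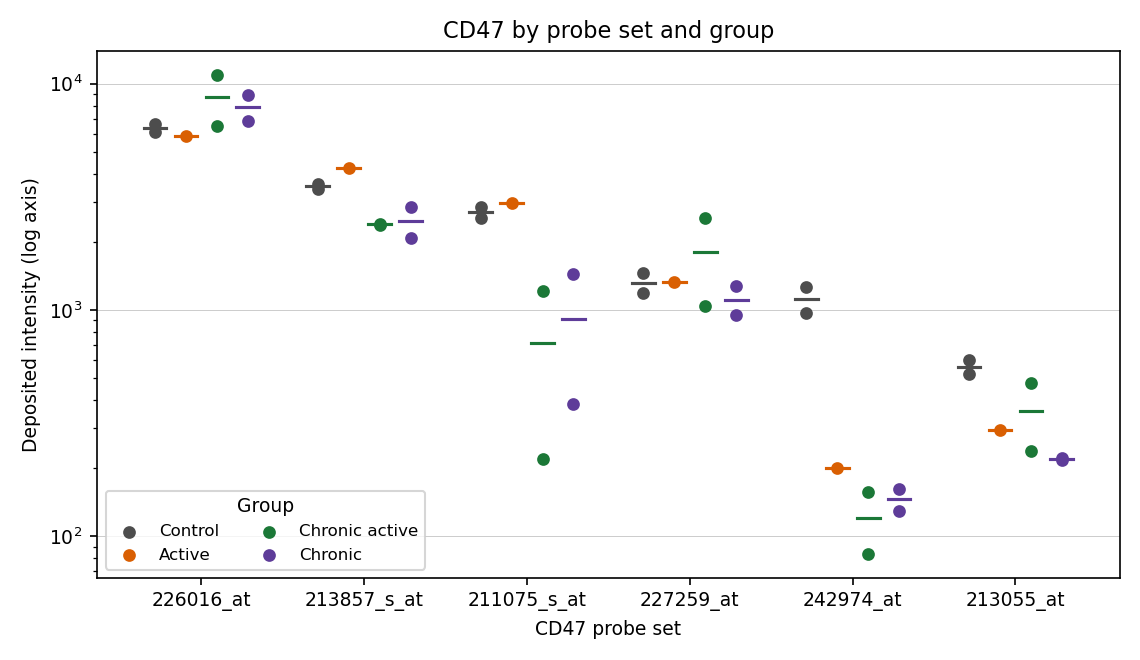
Intensity (log axis) of each CD47 probe set on each of the 7 arrays, as points coloured by histology with a line at each group mean. The brightest, on the left, lies between 5886 and 10960 on all arrays, while the one that fell most lies at 974.4 or more in control and at 200.9 or less in every plaque array.

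Chronic active plaque was compared with control white matter to find what differed in a lesion class described as demyelinated and still inflamed. Neuronal and synaptic genes were higher and myelin genes lower. UNC13C, which primes synaptic vesicles, went from an intensity of 71.8 ± 12.9 in control, under 100 on both arrays, to 4197 ± 852 (SD, n = 2 each; log2 5.58, SE 0.45, adjusted p = 0.00249), and its log2 fold change was 5.85 with a pseudocount of 1 and 4.96 with 64. MAG, a myelin adhesion protein, went from 14030 ± 967 to 696.5 ± 539 (SD, n = 2 each), 23.3-fold lower (log2 -4.54, SE 1.09, adjusted p = 0.0305). TTR, the thyroxine carrier made by the choroid plexus, had the largest fall, from 44300 ± 8180 to 454.5 ± 597 (log2 -7.72, SE 1.30, adjusted p = 0.0105). The size of the TTR fall depended on the pseudocount, with -8.00 for 1 and -7.19 for 64. TTR was very bright in control, where the highest intensities of any probe set were 55784 and 59526. Whether tissue content of the control samples accounts for the TTR fall was not tested.

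The other genes with the largest rises were the sodium channel SCN2A (log2 5.51, SE 0.31), the GABA receptor subunit GABRB2 (5.39, SE 0.41), CSMD1 (5.32, SE 0.58), CREG2 (5.24, SE 0.33) and ANO3 (5.22, SE 0.47). Those with the largest falls besides TTR and MAG were TMEM165 (-4.99, SE 0.48), ALOX5AP (-4.59, SE 1.03), needed for leukotriene synthesis, CARNS1 (-4.53, SE 0.73), which makes carnosine, and the protease KLK6 (-4.31, SE 0.94). All of these passed with adjusted p between 0.00249 and 0.0305. CSMD1 read under 100 in both controls, and its log2 fold change was 5.62 with a pseudocount of 1 and 4.64 with 64, and ALOX5AP read under 100 on 1 chronic active array, with -4.77 and -4.18.

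Of 25 measured genes of myelin and mature oligodendrocytes, 19 fell, none rose and 6 did not pass, and 23 fell when adjusted over the list alone. Examples are the gap junction gene GJB1 (log2 -3.46, SE 0.32), the neuregulin receptor ERBB3 (-3.27, SE 0.31) and MYRF (-3.40, SE 0.32), the transcription factor of myelin genes. The list median was -3.22 (camera adjusted p = 1.54e-12, but adjusted p = 0.398 with an estimated correlation). Of 22 neuron genes, 16 rose and 6 did not pass, with 16 adjusted over the list alone. SYT1, a calcium sensor of transmitter release, rose by 3.54 (SE 0.25) and ELAVL4 by 4.11 (SE 0.38), and the list median was 2.603 (camera adjusted p = 4.1e-08, adjusted p = 0.315 with an estimated correlation). Of 19 synapse genes, 17 rose, also when adjusted over the list alone. They included SYN2 (3.73, SE 0.31), SYT4 (3.81, SE 0.34) and DNM1 (3.80, SE 0.34), and the median was 3.30 (camera adjusted p = 2.78e-10, adjusted p = 0.315 with an estimated correlation).

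Genes of microglia and of antigen presentation were lower in the same arrays. No immune list was called higher than in control, although the class is described as still inflamed. Neuron and synapse genes were higher on these arrays, and whether different tissue content of the samples accounts for the falls was not tested. Of 10 homeostatic microglia genes, 7 fell, also when adjusted over the list alone, among them OLFML3 (log2 -2.85, SE 0.52), SALL1 (-1.95, SE 0.38) and the growth factor receptor CSF1R (-2.02, SE 0.42). The median was -1.80 (camera adjusted p = 0.000175, adjusted p = 0.315 with an estimated correlation). Of 10 MHC class II genes, 4 fell and 9 fell when adjusted over the list alone. They were HLA-DMA (-2.64, SE 0.48), HLA-DMB (-1.93, SE 0.37), HLA-DRB1 (-3.21, SE 0.85) and, named after its values were seen, HLA-DQB1 (-1.39, SE 0.39). The list median was -2.36 (camera adjusted p = 0.000334, adjusted p = 0.513 with an estimated correlation). Probe sets of HLA genes bind alleles and close paralogs unequally, so the values of single HLA genes are uncertain.

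Of 13 complement genes, 5 fell, with 6 adjusted over the list alone: C3AR1 (log2 -1.84, SE 0.34), ITGAM (-1.84, SE 0.35), C1QC (-2.78, SE 0.56) and, named after their values were seen, C3 (-3.11, SE 0.68) and ITGB2 (-2.34, SE 0.60). The median was -1.84 (camera adjusted p = 0.00015, adjusted p = 0.513 with an estimated correlation). Of 12 reactive astrocyte genes, 5 fell, with 6 adjusted over the list alone. They were the matrix protein TNC (-3.85, SE 0.45), the small heat shock protein CRYAB (-1.79, SE 0.29), S1PR3 (-1.79, SE 0.32) and, named after their values were seen, CD44 (-3.70, SE 0.97) and TIMP1 (-1.75, SE 0.47). Their median was -1.77 (camera adjusted p = 0.00177, adjusted p = 0.425 with an estimated correlation). Of 19 phagocytic macrophage genes, 2 fell, NPC2 (-2.50, SE 0.48) and TYROBP (-2.38, SE 0.47), while 1 rose and 5 fell when adjusted over the list alone. The median was -1.08 (camera adjusted p = 0.00881, adjusted p = 0.425 with an estimated correlation). Of 7 chemokine, cytokine and adhesion genes, CXCL16 (-2.0, SE 0.35) and CXCL12 (-1.49, SE 0.39) fell, with 4 adjusted over the list alone (median -1.35, camera adjusted p = 0.0225, adjusted p = 0.425 with an estimated correlation). Of 9 MHC class I genes, HLA-G fell (-2.04, SE 0.53) and 0 fell when adjusted over the list alone (median -1.87, camera adjusted p = 0.0121, adjusted p = 0.524 with an estimated correlation).

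The astrocyte list was not called (median 0.18, camera adjusted p = 0.853), and its members went both ways. Of 17, the glutamate transporter SLC1A2 (log2 1.76, SE 0.31) and the gap junction gene GJB6 (2.54, SE 0.56) rose while the calcium-binding S100B fell (-2.38, SE 0.58), these 3 named after their values were seen, with 3 rising and 2 falling when adjusted over the list alone. The oligodendrocyte precursor list (median -0.48, camera adjusted p = 0.26) was not called either, although 2 of its 11 members, SOX10 (-2.10, SE 0.32) and OLIG2 (-1.45, SE 0.35), named after their values were seen, fell. Medians of the other lists, none called, were -1.15 for neutrophil and monocyte, -0.66 for endothelial, -0.83 for mural cell, -0.71 for interferon response, -0.77 for cholesterol synthesis and -0.78 for extracellular matrix genes. They were -0.97 for cell cycle, -0.80 for heat shock and immediate early, -0.13 for hypoxia, 0.50 for metallothionein and -0.07 for mitochondrial respiration genes. Of the 11 extracellular matrix genes, 1 rose and 2 fell. Without the filter on dim genes 3 of these lists were called lower, extracellular matrix (median -1.16, camera adjusted p = 0.00391, adjusted p = 0.268 with an estimated correlation; 2 of 25 rose and 3 fell), interferon response (-0.71, camera adjusted p = 0.0169, adjusted p = 0.367 with an estimated correlation) and neutrophil and monocyte genes (-1.34, camera adjusted p = 0.018, adjusted p = 0.445 with an estimated correlation).

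In total 1875 of 8573 genes passed in limma after Benjamini-Hochberg adjustment, 1249 higher and 626 lower, and 969 of them changed more than 4-fold. Centring each array on its median moved the median log2 fold change of all genes from 0.08 to 0.26 and the share of called genes that were higher from 66.6% to 78%. With the mean of a gene's probe sets the split was nearly even, 845 higher and 790 lower, and over every probe set it was 1890 and 1324, so the excess of higher genes depended on the processing. The count was 118 without control replicate 2, 192 without control replicate 1, 1134 without chronic active replicate 1, 855 with the replicate number as a block, 5183 with plaque arrays paired by their likeness as a block, chosen after seeing the data, and 3214 over every probe set.

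**Figure D3:**
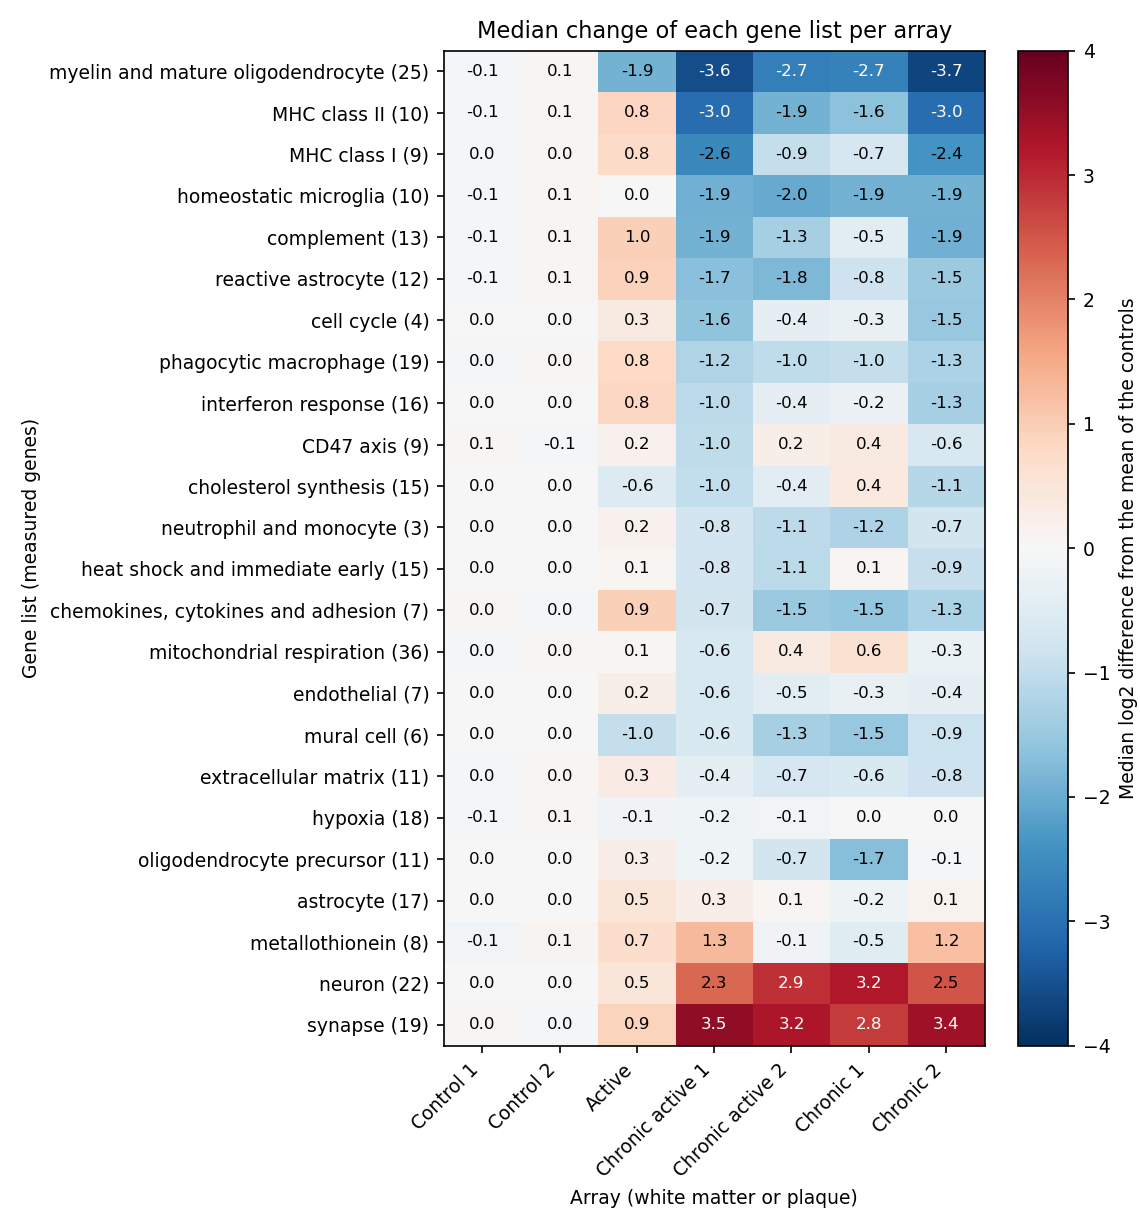
Median log2 difference from the mean of the controls for each fixed gene list on each of the 7 arrays, with the number of measured genes in brackets. Neuron medians lie between 2.29 and 3.21 on the 4 chronic active and chronic arrays and myelin medians between -3.67 and -2.70, while active plaque has positive medians for immune lists such as complement (0.95) and MHC class II (0.85).

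Chronic plaque was compared with control white matter to find what differed in a class whose inflammation is described as subsided. Neuronal genes were again higher and myelin and microglia genes lower. Tissue content of the samples was again not separated from a change in the lesions. The largest rises were UNC13C (log2 5.42, SE 0.45), the guanylate cyclase subunit GUCY1A2 (5.25, SE 0.39), the potassium channel KCNQ5 (5.21, SE 0.73), CREG2 (5.13, SE 0.33), GABRB2 (5.11, SE 0.41) and SCN2A (5.09, SE 0.31). The largest falls were TTR (-9.56, SE 1.30), at an intensity of 52.1 ± 49.8 (SD, n = 2), ECRG4 (-5.16, SE 1.08), TMEM165 (-5.00, SE 0.48), CARNS1 (-4.57, SE 0.73), KLK6 (-4.57, SE 0.94) and MAG (-4.38, SE 1.09). Their adjusted p lay between 0.00313 and 0.0371. The mean intensity was under 100 in control for UNC13C, GUCY1A2 and KCNQ5 and in chronic plaque for TTR, and 1 of the chronic arrays read under 100 for ECRG4, so these sizes and their order depend on the pseudocount. With a pseudocount of 1 or 64 the log2 fold change was -10.11 or -8.64 for TTR, 5.68 or 4.80 for UNC13C, 5.50 or 4.67 for GUCY1A2 and 5.46 or 4.63 for KCNQ5, while that of ECRG4 was -4.28 with 64 and could not be given with 1, where the gene fell under the filter.

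Of 25 myelin genes, 18 fell, with 24 adjusted over the list alone, including GJB1 (log2 -3.69, SE 0.32), PLEKHH1 (-2.94, SE 0.29) and ERBB3 (-2.91, SE 0.31). Their median was -2.94 (camera adjusted p = 2.2e-12, adjusted p = 0.398 with an estimated correlation). Of 11 oligodendrocyte precursor genes, the lineage transcription factors SOX10 (-1.97, SE 0.32) and OLIG2 (-1.49, SE 0.35) fell, also when adjusted over the list alone (median -0.98, camera adjusted p = 0.0491, adjusted p = 0.553 with an estimated correlation), but the list lost its call without the filter on dim genes (median -0.73, camera adjusted p = 0.0942). Of 22 neuron genes, 15 rose, with 17 adjusted over the list alone, such as SYT1 (3.70, SE 0.25) and the dendritic microtubule protein MAP2 (4.02, SE 0.39). The neuron median was 2.94 (camera adjusted p = 1.1e-09, adjusted p = 0.315 with an estimated correlation). Of 19 synapse genes, 17 rose, also when adjusted over the list alone, including SYN2 (3.50, SE 0.31), SYT4 (3.66, SE 0.34) and CPLX1 (3.35, SE 0.32), with a median of 3.145 (camera adjusted p = 2.78e-10, adjusted p = 0.315 with an estimated correlation).

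Of 10 homeostatic microglia genes, 7 fell, with 8 adjusted over the list alone, led by OLFML3 (log2 -3.59, SE 0.52), SALL1 (-2.41, SE 0.38) and SELPLG (-2.51, SE 0.42). Their median was -1.91 (camera adjusted p = 6.42e-05, adjusted p = 0.315 with an estimated correlation). Of 19 phagocytic macrophage genes, 3 fell, NPC2 (-2.29, SE 0.48), TYROBP (-2.11, SE 0.47) and APOC1 (-2.21, SE 0.50), and lipoprotein lipase, LPL, named after its values were seen, rose (1.49, SE 0.37). Adjusted over the list alone, 1 rose and 8 fell (median -1.17, camera adjusted p = 0.00971, adjusted p = 0.425 with an estimated correlation). Of 10 MHC class II genes, HLA-DMA (-2.62, SE 0.48), HLA-DQB1 (-1.76, SE 0.39) and HLA-DMB (-1.63, SE 0.37) fell, with 8 adjusted over the list alone (median -2.20, camera adjusted p = 0.000497, adjusted p = 0.513 with an estimated correlation). Of 13 complement genes, ITGAM (-2.08, SE 0.35), C3 (-2.99, SE 0.68) and C3AR1 (-1.32, SE 0.34) fell, with 4 adjusted over the list alone (median -1.29, camera adjusted p = 0.00192, adjusted p = 0.513 with an estimated correlation). None of 9 MHC class I genes passed, and 0 did when adjusted over the list alone (median -1.62, camera adjusted p = 0.0174, adjusted p = 0.551 with an estimated correlation).

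Of 12 reactive astrocyte genes, 4 fell: TNC (log2 -3.94, SE 0.45), CRYAB (-1.40, SE 0.29), S1PR3 (-1.39, SE 0.32) and, named after its values were seen, NES (-1.72, SE 0.47). Adjusted over the list alone, 5 fell (median -1.39, camera adjusted p = 0.0131, adjusted p = 0.471 with an estimated correlation). Of 7 chemokine, cytokine and adhesion genes, CXCL12 (-2.08, SE 0.39), CXCL16 (-1.68, SE 0.35) and CXCR4 (-1.99, SE 0.49) fell, with 4 adjusted over the list alone (median -1.40, camera adjusted p = 0.0237, adjusted p = 0.425 with an estimated correlation). Of 16 interferon response genes, IFI27 (-2.01, SE 0.44) and IRF9 (-1.46, SE 0.38) fell, and 0 did when adjusted over the list alone (median -0.52, camera adjusted p = 0.0449, adjusted p = 0.513 with an estimated correlation). None of 6 mural cell genes passed, although 2 fell when adjusted over the list alone. The one with the smallest p was MCAM (-1.52, SE 0.44, adjusted p = 0.0575), and the median was -1.23 (camera adjusted p = 0.0406, adjusted p = 0.425 with an estimated correlation). The mural cell list lost its call without the filter, where the median was -0.64 (camera adjusted p = 0.154).

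Within the astrocyte list (median -0.01, camera adjusted p = 0.853), SLC1A2 (log2 1.67, SE 0.31) and GJB6 (2.09, SE 0.56) rose and S100B fell (-2.50, SE 0.58), these 3 named after their values were seen, with 3 rising and 2 falling when adjusted over the list alone. Medians of the other lists, none called, were -0.98 for neutrophil and monocyte, -0.38 for endothelial, -0.40 for cholesterol synthesis, -0.996 for extracellular matrix and -0.91 for cell cycle genes. They were -0.40 for heat shock and immediate early, 0.39 for metallothionein and 0.17 for mitochondrial respiration genes. For hypoxia genes the median was 0.02 while the mean (-0.04) and the test pointed down. Of the 11 extracellular matrix genes, 1 rose and 3 fell, and without the filter on dim genes this list was called lower (median -1.49, camera adjusted p = 0.000741, adjusted p = 0.246 with an estimated correlation), with 8 of 25 members falling and 2 rising.

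In limma 1699 genes passed, 1107 higher and 592 lower, and 879 of them changed more than 4-fold. Chronic active and chronic plaque shared 1046 genes called higher and 502 called lower, and 0 were called in opposite directions, where independent lists would share 161.3 and 43.2. Draws of unchanged groups against the same controls shared 0 genes at most over 100 draws, but they held few calls to share (on average 0.13 in chronic active and 0.06 in chronic plaque), so this does not show how much of the overlap comes from shared controls. The log2 fold changes of the classes correlated across genes with r = 0.973, against 0.5 in those draws, and 91.7% of genes had the same sign against 66.7%. Their covariance was 1.64 against 0.113 simulated, a difference of 1.53. With chronic active plaque set against 1 control and chronic plaque against the other, a check chosen after seeing the data, the covariance was 1.629 and 1.625 in the 2 arrangements, r was 0.957 and 0.955, and 89.5% and 89.2% of genes had the same sign. Deviations of a single shared control array therefore do not account for the covariance. Because the controls resembled each other closely (r = 0.976), the check cannot exclude a shift common to both controls as a source. With only 1 control for each class the calls were not tested, and part of the excess overlap may come from sharing the controls. The draws were independent between classes, whereas the deviations of chronic active replicate 1 and chronic replicate 2 from their class means correlated at 0.745 across genes, so likeness of single arrays across the classes may also add to the overlap and covariance.

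Without either control replicate 1 or control replicate 2, the count for chronic plaque was 0 and so was the overlap, and with the replicate number as a block they were 691 and 647. The count was 2796 over every probe set and 4978 with plaque arrays paired by their likeness as a block, chosen after seeing the data, and median centring moved the median of all genes from 0.05 to 0.26 and the share called higher from 65.2% to 78.2%. The split was 763 higher and 716 lower with the mean of a gene's probe sets and 1652 and 1144 over every probe set.

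**Figure D4:**
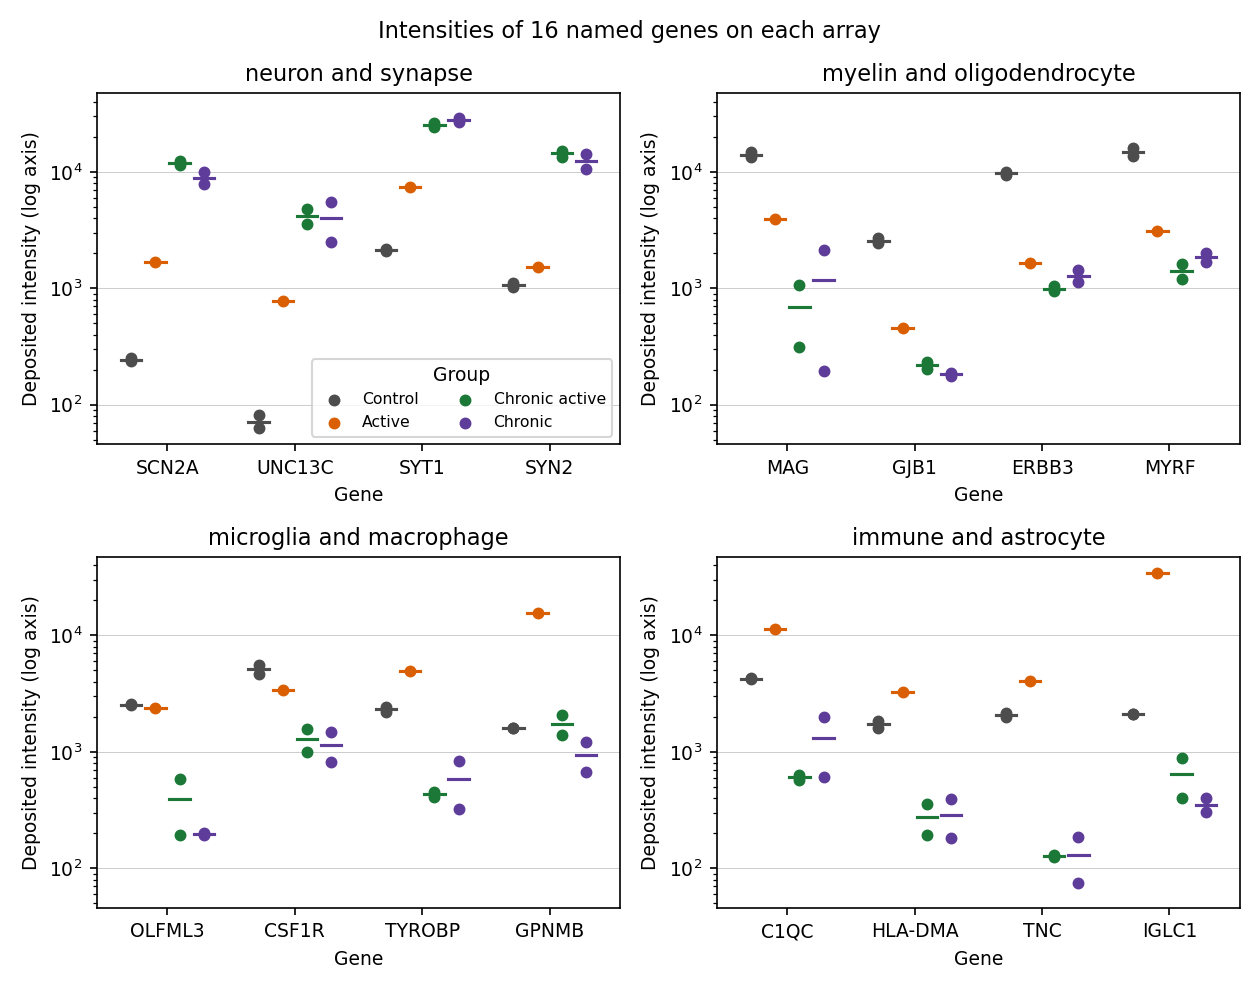
Intensity (log axis) of 16 named genes on each of the 7 arrays, as points coloured by histology with a line at each group mean. SCN2A has a mean of 243.5 in control, 1667 in active plaque, 11800 in chronic active and 8882 in chronic plaque, whereas GJB1 has means of 2557, 455.6, 218.5 and 182.7.

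Active plaque was compared with control white matter to find what differed at the early stage. The single array read higher for immunoglobulin light chain and macrophage genes and lower for oligodendrocyte genes, but no gene passed the test. IGLV1-44, a light chain segment, read 32240 against 731.5 ± 40.3 in control (SD, n = 2; log2 5.43, SE 0.54), and IGLC1 had a log2 fold change of 4.01 (SE 0.53). GPNMB, a glycoprotein of lipid-laden macrophages, read 15590 against 1594 ± 4.75 (SD, n = 2; log2 3.28, SE 0.50). The other genes with the smallest p were FBXW7 (3.13, SE 0.39), TMEM63A (-3.29, SE 0.43), SCN2A (2.70, SE 0.38), PCDH7 (2.43, SE 0.35), KITLG (3.02, SE 0.43), PIK3C2B (-2.62, SE 0.38), DAAM1 (3.07, SE 0.44), LRRN3 (3.27, SE 0.49) and ERBB3 (-2.54, SE 0.38). All of them had an adjusted p of 0.165. Immunoglobulin genes share near-identical sequence, so which of them was read is uncertain.

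Although no gene passed, camera called 10 gene lists at the preset correlation, and counts adjusted over the list alone are given with each. Their estimated correlations ran from 0.019 (astrocyte) to 0.798 (MHC class II), all above the preset. With 1 array, the p-values at the preset measure how the genes of a list moved against other genes, not the spread between samples. With the filter on dim genes at the 60th percentile 4 lists were called, and without the filter the mural cell list lost its call (median -0.42, camera adjusted p = 0.107) and the reactive astrocyte list gained one (0.91, camera adjusted p = 0.0321, adjusted p = 0.445 with an estimated correlation). All 25 myelin genes had negative log2 fold changes, and 7 fell when adjusted over the list alone, with a median of -1.88 (camera adjusted p = 1.43e-13, adjusted p = 0.398 with an estimated correlation). GJB1 (-2.45, SE 0.39) and PLEKHH1 (-2.06, SE 0.35) stood beside ERBB3. All 16 interferon response genes were positive, with 0 adjusted over the list alone, among them BST2 (1.49, SE 0.47), HERC6 (1.29, SE 0.46) and XAF1 (1.55, SE 0.70), and a median of 0.83 (camera adjusted p = 0.00592, adjusted p = 0.5 with an estimated correlation). Of 19 phagocytic macrophage genes, 17 were positive and 3 rose when adjusted over the list alone. GPNMB, LPL (2.13, SE 0.46) and the protease CTSS (1.60, SE 0.40) had the smallest p, and the median was 0.80 (camera adjusted p = 0.0146, adjusted p = 0.435 with an estimated correlation).

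Complement genes were positive in 12 of 13 cases, with 0 adjusted over the list alone, led by C1R (log2 1.81, SE 0.47), C1S (2.05, SE 0.68) and the inhibitor SERPING1 (0.95, SE 0.38), and a median of 0.95 (camera adjusted p = 0.0157, adjusted p = 0.553 with an estimated correlation). All 10 MHC class II genes were positive and 2 rose when adjusted over the list alone, with HLA-DQB1 at 2.22 (SE 0.48) and a median of 0.85 (camera adjusted p = 0.0491, adjusted p = 0.665 with an estimated correlation). The 7 chemokine, cytokine and adhesion genes were all positive, and 1 rose when adjusted over the list alone. They included the B cell survival factor TNFSF13B (2.45, SE 0.56), CXCR4 (1.64, SE 0.60) and CXCL12 (0.95, SE 0.47), with a median of 0.95 (camera adjusted p = 0.0222, adjusted p = 0.425 with an estimated correlation). Of 17 astrocyte genes, 4 rose when adjusted over the list alone, and the urea transporter SLC14A1 (2.24, SE 0.45), the water channel AQP4 (1.18, SE 0.30) and SLC1A3 (1.46, SE 0.37) had the smallest p (median 0.48, camera adjusted p = 0.0449, adjusted p = 0.425 with an estimated correlation).

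Synapse genes were positive in 16 of 19 cases, with 0 adjusted over the list alone. The glutamate receptor genes GRIN2A (log2 2.00, SE 0.56), GRIA2 (1.75, SE 0.57) and GRIA1 (1.43, SE 0.50) led, with a median of 0.91 (camera adjusted p = 0.0147, adjusted p = 0.513 with an estimated correlation). The 6 mural cell genes had a median of -0.96, with 0 adjusted over the list alone (camera adjusted p = 0.0174, adjusted p = 0.425 with an estimated correlation), and MCAM had a log2 fold change of -1.92 (SE 0.54). The 15 cholesterol synthesis genes had a median of -0.55, also with 0 adjusted over the list alone (camera adjusted p = 0.0222, adjusted p = 0.524 with an estimated correlation). DHCR7 (-1.75, SE 0.45), LSS (-1.48, SE 0.72) and HSD17B7 (-0.99, SE 0.62) led them.

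Medians of the lists that were not called were 0.48 for neuron, with 6 of 22 rising when adjusted over the list alone, 0.91 for reactive astrocyte, -0.01 for homeostatic microglia, 0.76 for MHC class I, 0.18 for neutrophil and monocyte, 0.34 for extracellular matrix, 0.08 for heat shock and immediate early, -0.13 for hypoxia and 0.70 for metallothionein genes. The test pointed down against a positive median for oligodendrocyte precursor (0.27), endothelial (0.24) and mitochondrial respiration genes (0.07), and for cell cycle genes, where the mean was also negative (0.35 against -0.20).

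After Benjamini-Hochberg adjustment limma called 0 genes, while 1239 had an unadjusted p under 0.05, 883 higher and 356 lower, in a fit that assumes the single array to vary like the replicated groups. A fit of only the compared groups, whose spread came from the 2 controls alone, called 4755 genes, a block of plaque arrays paired by their likeness, chosen after seeing the data, called 2398 (1633 higher, 765 lower), and median centring moved the median of all genes from 0.14 to 0.25.

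Active plaque was also compared with the mean of chronic active and chronic plaque, to find what set the early stage apart from the later ones. On the 1 active plaque array, complement and MHC class II genes read higher than in later plaque and neuronal genes lower. Light chain genes were among the largest rises. The largest rises were IGLV1-44 (log2 7.19, SE 0.49), IGLC1 (6.18, SE 0.48), the phospholipid-binding ANXA1 (5.59, SE 1.04), CAPS (5.09, SE 0.74), TNC (4.87, SE 0.50) and CYBA (4.397, SE 0.82), a subunit of the phagocyte NADPH oxidase. The largest falls were the neuronal protocadherin PCDH8 (-4.004, SE 0.63), ARPP21 (-3.71, SE 0.37), the immediate early gene EGR4 (-3.64, SE 0.77), PTPN5 (-3.62, SE 0.43), the GABA receptor subunit GABRD (-3.57, SE 0.71) and LRATD1 (-3.50, SE 0.40). Their adjusted p lay between 0.0289 and 0.0496.

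Of 13 complement genes, 6 rose, with 10 adjusted over the list alone, among them C1QC (log2 3.77, SE 0.63), C3AR1 (2.17, SE 0.38) and ITGAM (2.145, SE 0.39). Their median was 2.17 (camera adjusted p = 1.06e-07, adjusted p = 0.425 with an estimated correlation). Of 10 MHC class II genes, 4 rose, with 9 adjusted over the list alone: HLA-DQB1 (3.80, SE 0.43), CTSS (2.65, SE 0.37), HLA-DMA (3.54, SE 0.54) and, named after its values were seen, HLA-DMB (2.56, SE 0.41). The median was 3.53 (camera adjusted p = 1.12e-06, adjusted p = 0.5 with an estimated correlation). Of 19 phagocytic macrophage genes, 4 rose, with 9 adjusted over the list alone: GPNMB (3.64, SE 0.45), CTSS, TYROBP (3.33, SE 0.53) and, named after its values were seen, NPC2 (2.92, SE 0.54). This list had a median of 1.90 (camera adjusted p = 9.16e-07, adjusted p = 0.315 with an estimated correlation). Of 10 homeostatic microglia genes, OLFML3 (3.11, SE 0.58) and SELPLG (2.36, SE 0.47) rose, with 8 adjusted over the list alone (median 2.145, camera adjusted p = 5.3e-05, adjusted p = 0.315 with an estimated correlation).

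Of 7 chemokine, cytokine and adhesion genes, CXCL16 (log2 2.66, SE 0.39), CXCL12 (2.73, SE 0.43) and CXCR4 (3.32, SE 0.54) rose, with 6 adjusted over the list alone (median 2.12, camera adjusted p = 5.37e-05, adjusted p = 0.315 with an estimated correlation). Of 16 interferon response genes, BST2 rose (2.52, SE 0.43), with 5 adjusted over the list alone (median 1.53, camera adjusted p = 1.29e-05, adjusted p = 0.416 with an estimated correlation). Of 12 reactive astrocyte genes, TNC and S1PR3 (3.04, SE 0.36) rose, with 7 adjusted over the list alone (median 1.98, camera adjusted p = 1.23e-05, adjusted p = 0.381 with an estimated correlation). Of 9 MHC class I genes none passed, but 5 rose when adjusted over the list alone (median 2.42, camera adjusted p = 0.000235, adjusted p = 0.508 with an estimated correlation). Of 11 extracellular matrix genes, the collagen-binding SPARC rose (2.71, SE 0.47), with 4 rising and 1 falling when adjusted over the list alone (median 1.498, camera adjusted p = 0.00995, adjusted p = 0.398 with an estimated correlation).

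Of 22 neuron genes, 10 fell, with 18 adjusted over the list alone, including STMN2 (log2 -3.09, SE 0.37), SCN2A (-2.601, SE 0.34) and the neuronal enolase ENO2 (-2.42, SE 0.34). Their median was -2.02 (camera adjusted p = 1.55e-11, adjusted p = 0.315 with an estimated correlation). Of 19 synapse genes, 9 fell, with 17 adjusted over the list alone, such as SYN2 (-3.11, SE 0.34), CPLX1 (-2.94, SE 0.36) and SV2A (-2.66, SE 0.35), and the median was -2.39 (camera adjusted p = 2.2e-12, adjusted p = 0.315 with an estimated correlation). None of 25 myelin genes passed, and 0 did when adjusted over the list alone, with a median of 1.13 (camera adjusted p = 7.86e-05, adjusted p = 0.513 with an estimated correlation). None of 11 oligodendrocyte precursor genes passed on either count (median 0.54, camera adjusted p = 0.0491, adjusted p = 0.553 with an estimated correlation), and the list lost its call without the filter on dim genes (0.38, camera adjusted p = 0.136).

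The CD47 axis list was not called (median 0.41, camera adjusted p = 0.145), and neither was the astrocyte list (0.44, camera adjusted p = 0.087), of which SLC14A1 rose (log2 3.35, SE 0.41), named after its values were seen and the 1 gene also adjusted over the list alone. Medians of the other lists, none called, were 1.24 for neutrophil and monocyte, 0.28 for endothelial, 0.23 for mural cell, 1.14 for cell cycle, 0.90 for heat shock and immediate early, 0.12 for hypoxia and 0.20 for metallothionein genes. The test pointed down against a positive median for cholesterol synthesis (0.04) and mitochondrial respiration genes (0.06).

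Here limma called 468 genes, 181 higher and 287 lower in active plaque, and 362 changed more than 4-fold. The count was 0 without control replicate 1, control replicate 2, chronic active replicate 1 or chronic active replicate 2, 755 without chronic replicate 1, 0 over every probe set or with only the compared groups, and 3819 with plaque arrays paired by their likeness as a block, chosen after seeing the data. Median centring gave 307 genes and moved the share called higher from 38.7% to 24.4%, whereas without the filter on dim genes 425 were higher and 354 lower, so which direction held the majority depended on the filter.

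Chronic active and chronic plaque, described as lesions with ongoing inflammation and lesions without it, were compared, and no gene passed the test. The smallest p belonged to the immediate early gene JUNB, with an intensity of 335.4 ± 101 in chronic active and 1812 ± 1490 in chronic plaque (SD, n = 2 each; log2 -2.12, SE 0.63). It was followed by MBLAC2 (0.97, SE 0.35), DNAJC30 (0.89, SE 0.32), the chitinase-like CHI3L1 (-1.45, SE 0.53), the growth factor receptor FGFR3 (0.82, SE 0.31), ANKRD6 (0.96, SE 0.37), ERLIN1 (0.79, SE 0.31), ENHO (0.75, SE 0.29), SFRP2 (1.01, SE 0.40), the vasodilator peptide gene ADM (-1.06, SE 0.42), BMP7 (0.86, SE 0.34) and PCF11 (0.98, SE 0.39). All had an adjusted p of 1.

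Lists shifted by small amounts, and in each of the 9 called lists 0 members passed over all genes and 0 when adjusted over the list alone. Higher in chronic active plaque were oligodendrocyte precursor genes (median 0.31, camera adjusted p = 0.0121, adjusted p = 0.513 with an estimated correlation), such as PDGFRA (1.12, SE 0.65), and synapse genes (0.225, camera adjusted p = 0.0259, adjusted p = 0.513 with an estimated correlation), such as STX1A (0.69, SE 0.43). Lower were complement genes (-0.29, camera adjusted p = 0.000597, adjusted p = 0.513 with an estimated correlation), such as C1QA (-1.03, SE 0.70), and reactive astrocyte genes (-0.385, camera adjusted p = 0.00373, adjusted p = 0.425 with an estimated correlation), such as TIMP1 (-0.71, SE 0.47). Mitochondrial respiration genes were negative in 31 of 36 cases (median -0.28, camera adjusted p = 2.42e-05, adjusted p = 0.553 with an estimated correlation), with NDUFA9 at -0.59 (SE 0.39). Hypoxia genes were negative in 16 of 18 (median -0.285, camera adjusted p = 0.000271, adjusted p = 0.315 with an estimated correlation), with PDK1 at -0.60 (SE 0.36). Also lower were heat shock and immediate early genes (-0.21, camera adjusted p = 0.00177, adjusted p = 0.425 with an estimated correlation), with NR4A1 at -1.18 (SE 0.69), cholesterol synthesis genes (-0.25, camera adjusted p = 0.0157, adjusted p = 0.513 with an estimated correlation) and myelin genes (-0.16, camera adjusted p = 0.0467, adjusted p = 0.627 with an estimated correlation).

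Medians of the lists not called were 0.07 for CD47 axis, 0.09 for astrocyte, 0.14 for homeostatic microglia, -0.10 for phagocytic macrophage, -0.14 for MHC class I, -0.17 for MHC class II, -0.17 for neutrophil and monocyte, -0.16 for endothelial, 0.36 for mural cell and -0.18 for neuron genes. They were 0.21 for interferon response, 0.15 for extracellular matrix, -0.27 for cell cycle and 0.19 for metallothionein genes, and 0.05 for chemokine, cytokine and adhesion genes, where the test pointed down. Without the filter on dim genes, neutrophil and monocyte (-0.92, camera adjusted p = 0.00072, adjusted p = 0.365 with an estimated correlation) and cell cycle genes (-0.25, camera adjusted p = 0.0227, adjusted p = 0.321 with an estimated correlation) were also called lower.

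Limma called 0 genes after Benjamini-Hochberg adjustment, and 14 had an unadjusted p under 0.05, 11 higher and 3 lower. Among 8573 genes, chance alone would give far more at a share of 0.05. Each array of these classes correlated best with an array of the other class, which widens the spread within each class. The test was therefore conservative, and the low counts do not show that the classes were alike. With plaque arrays paired by their likeness as a block, chosen after seeing the data, the count was also 0. Without chronic replicate 1 the medians turned for cholesterol synthesis (0.38), complement (0.19), heat shock and immediate early (0.15), mitochondrial respiration (0.29), myelin (0.37) and oligodendrocyte precursor genes (-0.17), and without chronic active replicate 1 for cholesterol synthesis (0.23), mitochondrial respiration (0.18) and myelin genes (0.32). The 9 called lists depended on single plaque arrays. Without chronic replicate 1, 5 lists were called, of which 2 were among the 9. Without chronic active replicate 1, 7 were called with 3 among the 9, and without chronic active replicate 2, 6 with 4 among the 9, while 14 were called without chronic replicate 2, including all 9.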

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

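The tests of a passive rise of other cell types, of array scaling and of dim probe sets were chosen only after the results they bear on had been seen, and the lists of neuron subtype, choroid plexus and ependymal genes were written after the main comparisons had been seen.

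The first pattern is the rise of neuron and synapse genes with the fall of myelin genes in chronic active and chronic plaque. A lower share of oligodendrocyte RNA would raise all other cell types alike, but the neuron median exceeded the homeostatic microglia median by 4.41 on the log2 scale in chronic active and 4.84 in chronic plaque, which argues against it as the whole cause. Array scaling is also argued against, because the lowest neuron median over median centring and quantile normalization in both classes was 2.70. A candidate explanation is more neuron-bearing tissue, such as grey matter, in these plaque samples than in the control white matter. Of 30 listed markers of cortical neuron subtypes, 18 passed the filter, which uses the mean over all arrays and so favours markers high in plaque. These 18, none in the fixed lists, had a median log2 fold change of 2.30 or more in both classes. In limma 14 rose in chronic active and 10 in chronic plaque, while PVALB had -1.39 and -0.52. The brightest, MEF2C, HTR2A and NRN1, read 9369, 5222 and 4626 in chronic active plaque against 1026, 289.5 and 942.1 in control. As these are further neuronal genes, their rise cannot tell tissue content from a change in the lesions. All 18 also read at least 100 in control, the labels do not say where the lesions lay, and a change within the lesions themselves stays open as untested.

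The second pattern is the crossed likeness of the plaque arrays. The deviation of chronic active replicate 1 from its group mean followed the change from control to plaque with r of only 0.135 across genes (0.234 for chronic replicate 2). That was under the limit set beforehand, but 1 correlation over all genes cannot exclude different shares of neuronal tissue. Relative to control, neuron medians were 2.29 and 2.52 on these arrays against 2.93 and 3.205 on the other crossed pair. Myelin medians were -3.56 and -3.67 against -2.75 and -2.70. Synapse medians went the other way from neuron medians, with 3.54 and 3.40 against 3.23 and 2.79. After quantile normalization the deviations of chronic active replicate 1 and chronic replicate 2 still correlated at 0.755 (0.745 as deposited), which argues against intensity distributions. Effects specific to single probe sets stay open, since the deviations of the 2 brightest probe sets of a gene correlated at 0.514 (95% interval 0.491 to 0.537, 3908 genes), against 0.717 for the change from control to plaque and 0.145 for the difference between the controls. The interval treats genes as independent, which they are not, so it does not measure the spread between samples. Splitting the 4 plaque arrays across the labels called 3935 genes while the labelled split and the split by replicate number each called 0 in limma (14 and 90 at an unadjusted p under 0.05). The crossed split was taken from the likeness itself, so its count decides nothing, and a shared donor, a shared processing day and 1 array of each class carrying the other's label cannot be told apart.

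The third pattern is that the probe sets of CD47 changed by different amounts. Their log2 fold changes spanned 3.51 in chronic active and 3.10 in chronic plaque. Among 536 genes with 5 to 7 probe sets, whose median range was 2.30 and 2.13, the CD47 range was wider than most, at percentiles 85.4 and 82.4, but inside the central 95% set beforehand, so general disagreement between probe sets is a candidate explanation. The 4 CD47 probe sets with a mean of at least 1000 still spanned 2.74 and 2.11. Most of this span came from 1 of them, at -2.34 and -1.83, which read 218.6 on chronic active replicate 1 and 384.8 on chronic replicate 2. It read 1209 on chronic active replicate 2 and 1443 on chronic replicate 1, against 2550 and 2852 in control. The size of its fall therefore differed between arrays of one class and followed the crossed pairs. The other bright probe sets lay between -0.554 and 0.405 in chronic active and between -0.524 and 0.287 in chronic plaque. The probe set with the largest fall was too dim to enter this test. Dim probe sets therefore stay open as an explanation. Where each probe set lies along the CD47 transcripts was not examined, so a change in transcript form stays untested.

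Probe sets without a gene name, which entered only the alternative that tested every probe set, also changed. Of 1800 unnamed among 20002 probe sets tested in limma, 220 passed in chronic active plaque (136 higher, 84 lower) and 194 in chronic plaque (129 higher, 65 lower).

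For 9 gene lists the active plaque array lay above control while the medians of both later classes lay below it, and the difference between active and later plaque was called by camera with the preset correlation but not with an estimated one. The median log2 difference was 3.53 for MHC class II, 2.42 for MHC class I, 2.17 for complement, 2.12 for chemokine, cytokine and adhesion, 1.98 for reactive astrocyte, 1.90 for phagocytic macrophage, 1.53 for interferon response, 1.498 for extracellular matrix and 0.54 for oligodendrocyte precursor genes. Without the filter on dim genes, oligodendrocyte precursor genes leave this pattern, with a median of 0.08 in chronic active plaque against control and a difference of 0.38 between active and later plaque (camera adjusted p = 0.136). Other tissue markers moved in the same comparison, with medians of -2.02 for neuron, -2.39 for synapse and -2.17 for neuron subtype genes and 2.95 for 5 ependymal genes. Active plaque was represented by 1 array, and different tissue content of the samples and a difference between persons stay open beside one between lesion stages, as none of these was tested for the 9 lists.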

How the results depend on the processing

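Directions held widely but counts did not, in part because many alternatives could not change the direction of a named gene. The filters, no variance trend, only the groups compared, the replicate block and every probe set leave the log2 fold change of a probe set as it was. So does leaving out an array outside the comparison. The alternatives were chosen before the data were examined except the crossed pairing of plaque arrays and the replicate block with all arrays, which were added after seeing the data. Over the alternatives that kept all arrays, results for named genes were unchanged in direction and call 2180 times, lost their call 188 times, gained one 59 times and reversed 1 time (MYRF, 0.079 between chronic active and chronic plaque, under the mean of probe sets); list medians held 489 times and lost their call 34 times. With 1 array left out the same counts were 1166, 373, 22 and 13 for named genes, and list medians held 331 times, lost their call 22 times and reversed 9 times. The mean of probe sets reversed CD47 to -0.997 in chronic active, -1.07 in chronic and 0.54 in active against later plaque. Where no cause is given, the cause was not tested.

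Counts of called genes in limma moved as follows. Every probe set with its own test gave 3214 for chronic active plaque (1875 as reported), 2796 for chronic plaque (1699), 2533 for their overlap (1548) and 0 for active against later plaque (468). The replicate block, which leaves fewer degrees of freedom, gave 855, 691 and 647, and all 855 and 691 genes were among those reported, but the replicate numbers do not pair the arrays in their values. Active against later plaque gave 307 under median centring, 779 with no filter on dim genes, 298 with the filter at the 60th percentile and 0 with only the groups compared. Active plaque against control gave 4755 with only the groups compared, where the spread comes from the 2 controls alone, and 4 called lists in place of 10 with the filter at the 60th percentile, which tests fewer genes. The crossed pairing gave 5183, 4978, 2398 and 3819 genes for chronic active, chronic, active and active against later plaque. Chronic active against chronic plaque stayed at 0 genes throughout, with 14 at an unadjusted p under 0.05 as reported.

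Leaving out 1 array gave 118 (without control replicate 2) to 2401 (without chronic replicate 1) genes for chronic active plaque, with 192 without control replicate 1 and 1134 without chronic active replicate 1. It gave 0 (without either control) to 1849 for chronic plaque and 0 to 1552 for the overlap. Active against later plaque ranged from 0 (without control replicate 1 or 2, or chronic active replicate 1 or 2) to 755 (without chronic replicate 1). Called lists between chronic active and chronic plaque ranged from 5 to 14, and the CD47 difference from -0.257 to 0.492.

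With 1 array left out, single genes reversed only between chronic active and chronic plaque, where besides CD47 the log2 fold change ranged from -2.449 to 0.188 for ACAT2, -2.06 to 0.153 for ATF3, -1.387 to 0.225 for ATP5F1A, -1.704 to 0.004 for C1QC, -1.66 to 0.279 for FDPS, -0.159 to 1.085 for GRIA2, -1.53 to 0.379 for INSIG1, -1.353 to 0.016 for MAL, -1.399 to 0.012 for NDUFV1 and -0.133 to 1.854 for OLIG1. List medians ranged from -1.329 to 0.379 for cholesterol synthesis, -0.762 to 0.193 for complement, -1.014 to 0.153 for heat shock and immediate early, -0.821 to 0.292 for mitochondrial respiration, -0.717 to 0.367 for myelin and -0.167 to 0.782 for oligodendrocyte precursor genes. Lists were not run over every probe set, and ECRG4 had no value with a pseudocount of 1, where it fell under the filter. The planned replicate block left out active plaque, which carries no number. With all arrays and active plaque at the middle of the block it gave 868 genes for chronic active, 691 for chronic, 0 for active and 0 for active against later plaque. Contrasts with active plaque could not be fitted without that array. Probe sets under an intensity of 100 made up 12.8% to 24.8% of an array, and low signal limits what can be said of dim genes.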

Other observations

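The comparison of ependymal, choroid plexus and neuron subtype genes and the other pseudocounts for lymphocyte genes were chosen only after the main results had been seen, and the genes named here were chosen after their values were seen.

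Most lymphocyte genes were too dim for the filter. Without it they read higher on the 1 active plaque array by their medians, B and plasma cell genes more than T cell genes. Of 17 measured B and plasma cell genes, 10 were higher in active than in later plaque in limma, including the heavy chain gene IGHM (log2 8.31, SE 0.58, adjusted p = 0.0118), JCHAIN (7.81, SE 1.17, adjusted p = 0.0259), which joins antibody chains, and MZB1 (4.61, SE 0.73, adjusted p = 0.0266), while IGHG1 (0.84, adjusted p = 0.58), IGHA1 (3.90, adjusted p = 0.0566) and IGKC (4.43, adjusted p = 0.0638) did not pass. Each of these 3 called genes read under 100 on 3 of the 4 later arrays, and their intensities in active, chronic active and chronic plaque were 32840, 151.2 and 54.94 for IGHM, 27450, 436 and 47.11 for JCHAIN and 2307, 92.6 and 77.46 for MZB1. The sizes depended on the pseudocount, with 8.58 for 1 and 7.72 for 64 in IGHM, 8.11 and 7.19 in JCHAIN and 4.87 and 4.03 in MZB1. Of the 10 genes, 6 passed with a pseudocount of 1 and all with 64. The list median was 3.88 (camera adjusted p = 3.7e-11, adjusted p = 0.27 with an estimated correlation), and 2.93 against control (camera adjusted p = 1.36e-11, adjusted p = 0.268 with an estimated correlation), where 0 members passed. Of 16 T cell genes, CD4 (2.14, SE 0.46, adjusted p = 0.0461) and the interleukin receptor IL7R (3.33, SE 0.62, adjusted p = 0.0352) rose against later plaque, but neither passed with a pseudocount of 1 (adjusted p = 0.0527 and 0.667, the latter on another probe set). IL7R read under 100 on all 4 later arrays. The median was 2.28 (camera adjusted p = 5.66e-06, adjusted p = 0.371 with an estimated correlation). Against control the T cell median was 1.58 (camera adjusted p = 0.000807, adjusted p = 0.455 with an estimated correlation). CD4 is also made by microglia and macrophages.

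In chronic plaque the T cell median was -0.99 against control (camera adjusted p = 0.0204, adjusted p = 0.56 with an estimated correlation), and CD4 (log2 -2.22, SE 0.41, adjusted p = 0.0156) and IL7R (-2.18, SE 0.55, adjusted p = 0.0403) fell. IL7R read under 100 in control and in chronic plaque and passed with a pseudocount of neither 1 (adjusted p = 0.802, on another probe set) nor 64 (adjusted p = 0.0541). The B and plasma cell median was -0.70 (camera adjusted p = 0.0716), and IGHM (-1.959, SE 0.52, adjusted p = 0.0459, but 0.0558 with a pseudocount of 64) and IGLC1 (-2.54, SE 0.44, adjusted p = 0.0127) fell. In chronic active plaque the medians were -0.45 (camera adjusted p = 0.28), with 0 T cell members past the test, and -0.53 (camera adjusted p = 0.365), with IGLC1 falling (-1.80, SE 0.44, adjusted p = 0.0336). Chronic active exceeded chronic plaque by a median of 0.76 for T cell genes (camera adjusted p = 0.000814, adjusted p = 0.455 with an estimated correlation) and 0.62 for B and plasma cell genes (camera adjusted p = 0.00802, adjusted p = 0.511 with an estimated correlation), with 0 members past the test in either list. The 4 measured red cell genes were not called, with medians of -1.04 in chronic active, -0.99 in chronic and -0.44 in active plaque.

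Of 5 measured genes of ciliated ependymal cells, which line the ventricles, CAPS, RSPH1 and TPPP3 were higher on the 1 active plaque array than in later plaque, while DNALI1 (adjusted p = 0.0592) and MORN2 (adjusted p = 0.16) did not pass. Their median log2 difference was 2.95, and the medians against control were 1.49 in active plaque, where 0 passed, and -1.12 in chronic active and -1.57 in chronic plaque, where CAPS and TPPP3 fell. The list was not tested as a set. CAPS read 12400 in active plaque against 3838 in control, 417.2 in chronic active and 372.8 in chronic plaque, and RSPH1 read 5466 against 1403, 640.8 and 786.7. Choroid plexus genes went both ways: of 7 measured, CAB39L and STEAP2 rose and TTR and AQP1 (-3.57, SE 0.64, adjusted p = 0.0124) fell in chronic active plaque. In chronic plaque the same genes rose, and TTR, AQP1 (-3.28, SE 0.64, limma adjusted p = 0.0171) and ECRG4 (-5.16, SE 1.08, limma adjusted p = 0.0221) fell. TTR read 44300 in control, 1847 in active and 454.5 in chronic active plaque, while FOLR1 read 1713, 2028 and 1367. All 7 choroid plexus and all 5 ependymal genes read at least 100 in control.

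Median changes of several lists differed between arrays of one plaque class. Relative to the control mean, mitochondrial respiration genes had medians of -0.65 and 0.36 in the chronic active arrays and 0.62 and -0.28 in the chronic arrays, and metallothionein genes 1.31 and -0.14 against -0.50 and 1.20. MHC class I medians were -2.56 and -0.94, and -0.67 and -2.39. Neuron subtype genes differed less, with medians of 2.25, 2.66, 2.23 and 2.35 on the same arrays.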
